A study of Mus musculus with 24 samples.

How the data were processed

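The deposited scanner tables, written by Agilent Feature Extraction 10.5.1.1 per the file headers, hold for each spot and each dye the mean and median signal and the local background, all in raw intensity units. The deposited series table holds 1 linear intensity per probe spot and sample, with medians of 102 to 107.7 over the 24 columns. Each column correlated with the median signal of its own dye at 0.9988 or more across spots, and with the other dye of the array at 0.9978 or less. No spot was saturated, 0.446% of values carried a non-uniformity or population outlier mark and were left out, and 54.26 to 65.87% of the spots of a sample were well above background. The median raw signal of a sample lay between 65 and 163.5.

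The mean signals were analysed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Background was corrected by normexp with an offset of 50, with the local background median as estimate. The 1639 control spots were then removed, which left 43379 spots. Loess within arrays and Aquantile normalization between arrays followed, and the values became log2 intensity per dye. Spots of the same probe were averaged to 41174 probes, of which 24375 took their gene symbol from the transcript accession, 6301 from the symbol and 2426 from a synonym in the RefSeq reference, while 8072 kept the name in the file. Probe positions are those of the file, on the mm8 build. Of the 27597 gene names, 8942 had several probes, and the probe with the highest mean stood for the gene. Genes had to be well above background in all 4 samples of at least 1 group. This left 16241 genes, 13213 of them with a gene symbol, and removed 11356.

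Each array held 2 samples, so the dyes were fitted as separate channels with an intraspot correlation of 0.454, estimated across genes. The model had a mean for each of the 6 groups and a dye term, with 17 residual degrees of freedom and 5.14 prior degrees of freedom from the empirical Bayes step. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The tests of single genes are the two-sided moderated statistics of limma. Fitted fold changes include the dye term and the array correlation, so they can differ from the difference between printed group means. These p-values measure only the spread between these samples. The design text calls them biological replicates, but nothing says whether they came from separate cultures or from more than 1 clone of each construct.

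The 28 gene lists held 1107 genes, of which 1100 were on the array and 982 were tested. They covered cobalamin uptake and handling, folate, methionine and serine metabolism, arginine methyltransferases and PP2A, sirtuins and histone or DNA methylation enzymes, RNA binding proteins of mRNA stability and stress granules, mRNA export and the nuclear pore, hnRNP and SR splicing factors, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, cholesterol and fatty acid synthesis, DNA replication and G1/S, mitosis and G2/M, p53 targets and apoptosis, the integrated stress response, the unfolded protein response and ER chaperones, heat shock, oxidative stress and Nrf2 targets, interferon and antiviral genes, immediate early and serum response genes, neuronal structure and synapse, ion channels and neurotransmitter receptors, axon guidance and growth, catecholamine and cholinergic identity, extracellular matrix and adhesion, and markers of glia, of blood and endothelium, and of fibroblast and smooth muscle. Each list was compared with the other genes by camera at a preset correlation of 0.01, with p adjusted over the 28 lists of a comparison.

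The genes named were set by rule. For each pair of groups they were the 10 with the largest change in each direction among called genes with a symbol and with all samples of one group beyond all of the other, which were 4 or, where a spot was left out, 3, and the text may print fewer of them. A few genes that these rules select are not reported here. For differences in the medium response the rule took 5 per direction, for genes apart from both other lines 10 per direction, and for a list at most 4 members. Genes not above background in one group were named separately, at most 3 per direction, with a lower bound on the fold, which is the group mean above background less the mean of the other group with each value raised to the lowest level well above background in its sample. With such genes at their bound, the medians of 86 lists between pairs of groups changed by at most 0.051. Tcn2, Cd320, Mtr, Mmachc, Elavl1, Sirt1, Ppp2ca, Hspa5, Ddit3 and Th were always read out.

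The groups, the model, the thresholds and the rule for named genes were fixed before the data were examined, as were these alternatives: the Feature Extraction processed signals less their 75th percentile, the values of the series table, quantile normalization, loess alone, no filter, every probe tested singly, no dye term, slide as a covariate, the replicate number as a block in place of dye, no array correlation, eBayes with trend and robust, only the groups compared, each sample left out in turn, and, for lists, an estimated correlation and fry. The 6 pairs of RNA labels that share a number, such as 1 and 1b, were also averaged or had their b sample left out. The labels do not say whether such a pair is the same RNA with the other dye.

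A further step was chosen after the first results were seen. On the array of TO-p replicate 4 the normexp fit with every spot gave a background SD of 4400 from 6 spots whose local background reached 525000. Spots with a local background above their own mean signal by more than 50 were therefore left out, 14 in all on 3 arrays, and that fit gave 2.22. The mean correlation of this sample with the other TO-p samples, after the mean of all samples was taken from each gene, went from -0.169 to 0.768, against 0.74 with the processed signals and 0.754 with the series table. A fit with every spot, and one without the WT-p samples of RNA label 1, were also added after the data were seen.

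The procedure was tested on simulated data with 15835 genes, 200 of them changed in a comparison. Changes of log2 0.5 were recovered in 58.6 to 84.4% of cases and changes of log2 1 in 97.1 to 100%, with 4 to 18 false calls per comparison. With no changed genes there were 0 calls, and a correlation of 0.4 was estimated as 0.432. Replicate numbers were checked for pairing. In TO against WT in differentiation medium the samples of like number correlated at 0.139 to 0.261 after the group means were removed, and at -0.0921 to 0.14 once the dye was removed too, and the numbers contain the dye.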

Results

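Gene expression was measured in N1E-115, a mouse neuroblastoma line used as a model of neurons, on 12 Agilent 2-colour mouse arrays on 3 slides. The untransfected line (WT) was compared with lines carrying fusions of transcobalamin, the carrier of cobalamin, and oleosin, a protein that anchors in lipid membranes. Per the design text, TO carries transcobalamin at the N-terminus and binds cobalamin strongly, while OT carries it at the C-terminus and shows no detectable binding. Each line was grown in proliferation medium (p, 10% serum) and in differentiation medium (d, 2.5% serum and 1.25% DMSO), which made 6 groups of 4 samples, 24 in all. Every group had 2 samples in Cy5 and 2 in Cy3, and each array held 2 samples. The labelling reactions started from 0.2 µg of RNA. Levels are normalized log2 intensity with the SD over 4 samples, or 3 where a spot was left out, and the number of arrays limits their precision.

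The first readout was the genes of the pathway that the fusions target. Tcn2, which encodes transcobalamin itself, was 2.63-fold higher in TO-p (8.97 ± 0.082, SD, n = 4) than in OT-p (7.58 ± 0.0673), with WT-p at 7.90 ± 0.231 (limma adjusted p = 8e-11). It was 1.33-fold higher in TO-d than in OT-d (adjusted p = 0.00348) and higher than in WT-d by log2 0.58 (adjusted p = 0.000234). Its probe lies on chromosome 11 at 3822050 to 3822109, and whether it also reads the construct's transcript is not known from the labels. Mtr, the cobalamin-dependent methionine synthase, was 1.54-fold higher in TO-d (8.26 ± 0.196) than in OT-d (7.59 ± 0.187), adjusted p = 2.01e-05. In proliferation medium Mtr did not pass the threshold (log2 -0.13, adjusted p = 0.235). Mmachc, which processes cobalamin inside the cell, was 1.31-fold lower in TO-p than in OT-p (adjusted p = 0.00568). Cd320, the receptor for loaded transcobalamin, was not called between TO-p and OT-p (adjusted p = 0.636) and was 1.79-fold lower in OT-d (10.63 ± 0.21) than in WT-d (11.49 ± 0.323), adjusted p = 5.87e-07. It was also 1.42-fold lower in TO-d than in WT-d (adjusted p = 0.00121) and 1.26-fold higher in TO-d than in OT-d (adjusted p = 0.0201).

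Genes of mRNA transport and its regulators were read out in the same way. Elavl1, which encodes the mRNA-binding protein HuR, was 1.17-fold higher in TO-p than in OT-p (log2 0.23, adjusted p = 0.0236). The call was lost without TO-p replicate 3 (adjusted p = 0.101), OT-p replicate 2 (0.0588) or OT-p replicate 4 (0.0619), and the 3 probes of Elavl1 went different ways (log2 0.23, 0.14 and -1.50). Sirt1, a deacetylase, was 2.19-fold lower in TO-p (9.59 ± 0.218) than in OT-p (10.72 ± 0.14), adjusted p = 8.14e-10. Sirt1 was also 1.71-fold lower in TO-d than in OT-d, 1.38-fold lower in TO-p than in WT-p and 1.30-fold lower in TO-d than in WT-d, and it was 1.59-fold higher in OT-p than in WT-p. Ppp2ca, the catalytic subunit of PP2A, was 1.35-fold lower in TO-p than in OT-p (adjusted p = 8.98e-05), while TO-p did not pass against WT-p (adjusted p = 0.954) and OT-p was 1.34-fold above WT-p. Hspa5, the main chaperone of the endoplasmic reticulum, was 1.56-fold higher in TO-d (15.28 ± 0.155) than in OT-d (14.71 ± 0.0825), adjusted p = 1.8e-06, and 1.65-fold higher than in WT-d. Ddit3, a transcription factor of the stress response, was 2.25-fold higher in TO-p (12.80 ± 0.0566) than in OT-p (11.68 ± 0.0852) and 2.22-fold higher in TO-d than in OT-d (adjusted p = 2.28e-08 and 1.8e-07). TO-d did not pass against WT-d in Ddit3 (adjusted p = 0.978), and OT-d was 2.21-fold lower than WT-d (adjusted p = 5.59e-08). Th, the first enzyme of catecholamine synthesis, was 1.57-fold lower in TO-d (12.29 ± 0.081) than in OT-d (12.88 ± 0.113), adjusted p = 3.08e-06, where TO-d did not pass against WT-d (adjusted p = 0.867) and OT-d was 1.54-fold above WT-d.

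**Figure D1:**
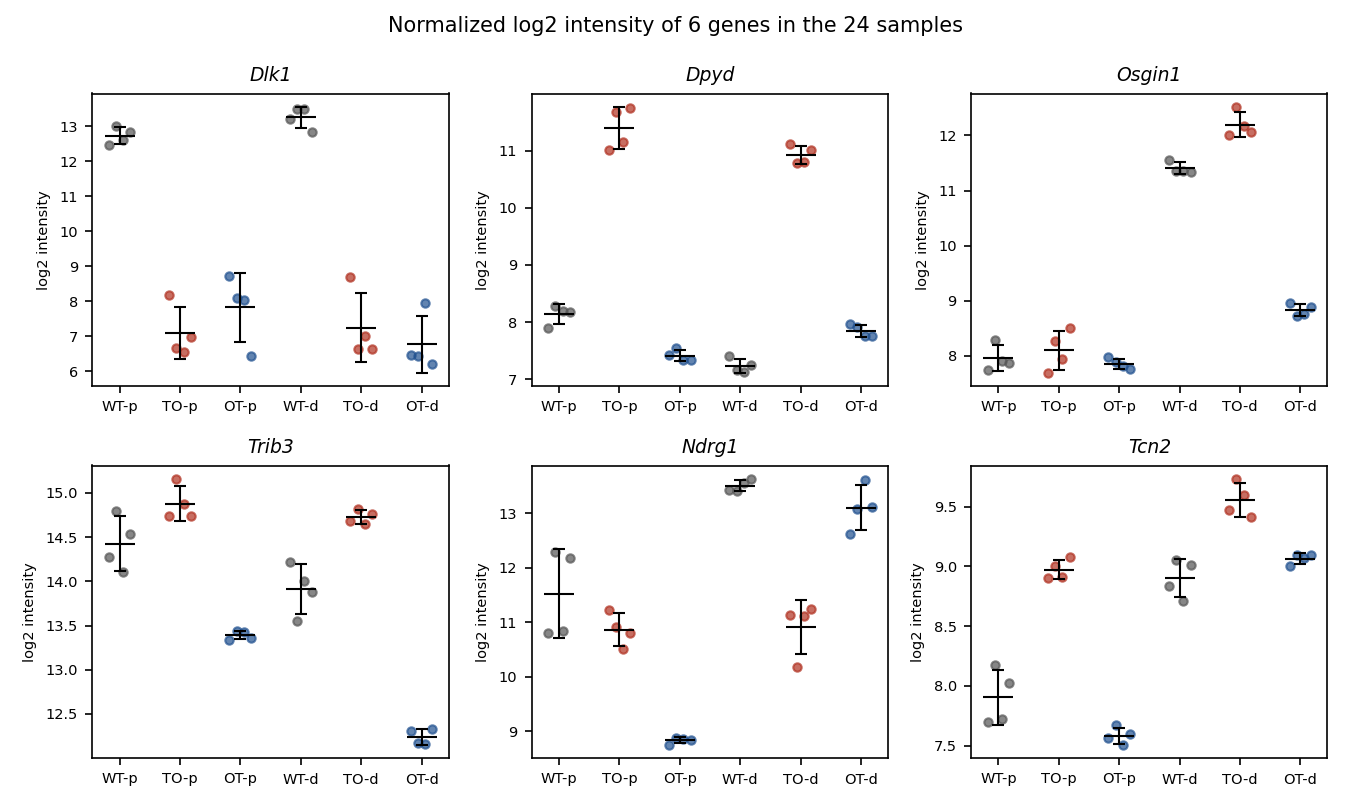
Normalized log2 intensity (vertical axis) of 6 genes in the 6 groups (horizontal axis), with each point a sample and the black bars the mean and SD of 4 samples. Dlk1 is at 12.73 in WT-p against 7.10 in TO-p and 7.83 in OT-p, Dpyd is highest in TO in either medium, and Trib3 is lowest in OT-d at 12.24.

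TO against OT in proliferation medium compares the line that binds cobalamin with the line whose fusion does not. Dpyd, which breaks down pyrimidines, was 15.6-fold higher in TO-p (11.39 ± 0.37, SD, n = 4) than in OT-p (7.41 ± 0.097), adjusted p = 3.55e-17. Slc7a14, a transporter-like protein of lysosomes, was 14.2-fold higher (14.56 ± 0.299 against 10.75 ± 0.0683), and St3gal1, a sialyltransferase, was 13.0-fold higher (10.86 ± 0.299 against 7.32 ± 0.234). Pcolce, an enhancer of procollagen cleavage, was 12.6-fold higher (13.71 ± 0.123 against 10.05 ± 0.0535), adjusted p = 1.29e-21. The glycolytic enzyme Aldoc (10.0-fold), the microtubule protein Eml2 (8.45-fold), the dehydrogenase Bdh2 (8.35-fold), the vascular factor Angpt2 (8.27-fold) and the sterol reductase Tm7sf2 (7.94-fold) came next, with SDs of 0.256 to 0.443 in TO-p.

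The gene furthest lower in TO-p than in OT-p was Gpm6b, a membrane protein of neurons and glia, at 19.3-fold (6.86 ± 0.311 against 11.14 ± 0.158, SD, n = 4; adjusted p = 3.19e-16). Galnt5, which starts O-glycosylation of mucins, was 7.91-fold lower, and Wnt2, a secreted growth signal, was 7.06-fold lower (8.10 ± 0.237 against 10.90 ± 0.0828). The melanoma antigen genes Magea8, Magea3, Magea1 and Magea6, near-identical relatives on the X chromosome that probes may not tell apart, were 6.53- to 7.40-fold lower. Bambi, a decoy receptor of TGF-beta signals, was 6.94-fold lower, the lipase inhibitor Angptl4 6.23-fold and Ddc, which makes dopamine, 5.62-fold lower (7.74 ± 0.105 against 10.23 ± 0.101). Izumo3 was above background only in OT-p, at least 8.17-fold above TO-p, and Cdyl2 only in TO-p, at least 3.19-fold above OT-p. In all, 4870 genes were higher and 4266 lower in TO-p, with 865 and 294 over 2-fold, and 4522 were higher and 3789 lower with loess alone. Within each slide the differences correlated at 0.937 to 0.969 with the pooled ones across genes, which are not independent replicates.

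Growth genes were lower in TO-p than in OT-p. Of 46 DNA replication genes 36 were lower and 1 higher (median log2 -0.70, adjusted p = 4.26e-09; adjusted p = 0.441 with an estimated correlation), led by Rpa2 (3.02-fold), which coats single-stranded DNA, the uracil glycosylase Ung (2.94-fold) and the licensing factor Cdc6 (2.83-fold). Of 46 mitosis genes 27 were lower and 1 higher (median -0.44, adjusted p = 5.61e-05; 0.506 with an estimated correlation), among them the kinases Cdk1 and Plk1 (log2 -0.94 and -0.80). Genes of RNA handling lay on the same side. Of 52 splicing factors 33 were lower, including Hnrnpdl (log2 -1.21) and Rbm3 (log2 -1.14), and 3 higher, led by the neuronal splicing regulator Ptbp2 at log2 1.46 (median -0.37, adjusted p = 7.13e-06; 0.341 with an estimated correlation). Of 62 mRNA export and nuclear pore genes 39 were lower and 5 higher, with the pore protein Pom121 at log2 -1.08 and the export helicase Ddx39a at -1.02 (median -0.34, adjusted p = 2.77e-05; 0.341 with an estimated correlation). Of 43 RNA-binding genes of mRNA stability 21 were lower and 5 higher, with the oncofetal mRNA-binding gene Igf2bp3 6.00-fold lower and Tial1 at log2 -1.45 (median -0.20, adjusted p = 0.00522; 0.341 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.18, 25 of 51 lower and 9 higher, with Sdhd at log2 -0.82 (adjusted p = 0.0139; 0.506 with an estimated correlation).

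Antiviral, neuronal, glycolysis, stress, cholesterol and matrix genes were higher in TO-p than in OT-p. Of 32 interferon genes 26 were higher and 3 lower (median log2 0.70, adjusted p = 3.29e-06; 0.341 with an estimated correlation), with the RNA sensor Oas1a at log2 2.29 and the ubiquitin-like modifier Isg15 at 2.17. Of 50 neuronal genes 29 were higher and 5 lower (median 0.31, adjusted p = 0.00247; 0.341 with an estimated correlation), led by the neuronal enolase Eno2 (log2 1.85), the adhesion molecule Nrcam (1.44) and the microtubule protein Mapt (1.28). Glycolysis and hypoxia genes were higher in 24 of 39, with Aldoc, Ndrg1 (log2 2.15) and the glucose transporter Slc2a3 (1.57) on top (median 0.48, adjusted p = 0.0052; 0.563 with an estimated correlation). The integrated stress response was higher in 15 of 30, led by Trib3 (log2 1.49) and Ddit4 (1.35), median 0.33, adjusted p = 0.00522 (0.341 with an estimated correlation). Cholesterol synthesis genes were higher in 20 of 36, with Acss2 at log2 1.87 (median 0.32, adjusted p = 0.0337; 0.538 with an estimated correlation), and matrix genes in 17 of 35, with Col1a1 at 1.62 (median 0.24, adjusted p = 0.00821; 0.441 with an estimated correlation). Adjusted over the list alone, 37 replication genes were lower and 4 splicing factors higher, and the other counts of export, mitosis, RNA-binding and interferon genes were the same.

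The lists of cobalamin genes, of arginine methyltransferases and PP2A, and of sirtuins and methylation enzymes were not called between TO-p and OT-p. Of 20 cobalamin genes 8 were higher, with the lysosomal transporter Abcd4 at log2 1.35, and 4 were lower (median 0.09, adjusted p = 0.302). Of 32 arginine methyltransferase and PP2A genes 15 were lower, led by Prmt6 (log2 -1.24), and 7 higher, led by Prmt7 (0.91), with adjusted p = 0.099. Sirtuins and methylation enzymes went both ways, 11 of 36 higher with Sirt5 at log2 1.38 and 12 lower with Sirt1 (adjusted p = 0.633). Markers of other cell types were not called either. The medians were 0.14 for glia (adjusted p = 0.582), 0.245 for blood and endothelium (adjusted p = 0.217) and 0.152 for fibroblasts and smooth muscle (adjusted p = 0.18).

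TO against OT in differentiation medium asks the same with the cells induced to differentiate. Osgin1, a target of the oxidative stress factor Nrf2, was 9.19-fold higher in TO-d (12.20 ± 0.23, SD, n = 4) than in OT-d (8.83 ± 0.105), adjusted p = 4.4e-14. Dpyd was 8.23-fold higher, Pcolce 6.65-fold and the matrix protein Tgfbi 5.63-fold, and the stress pseudokinase Trib3 was 5.53-fold higher (14.73 ± 0.0757 against 12.24 ± 0.0921; adjusted p = 3.99e-13). The histocompatibility gene H2-M3 (5.27-fold), Isg15 (5.22-fold), the kinesin Kif21b (5.19-fold), Ifit1 (5.11-fold) and Znhit6 (5.10-fold), which assembles small nucleolar particles, followed. Tmsb4x, which binds actin monomers, was 11.7-fold lower in TO-d (7.78 ± 0.125 against 11.32 ± 0.188; adjusted p = 1.61e-18). Wnt2 was 11.4-fold lower (7.76 ± 0.181 against 11.33 ± 0.0852), the angiotensin receptor Agtr2 11.4-fold (7.37 ± 0.11 against 11.39 ± 0.147) and Ddc 9.28-fold (8.18 ± 0.198 against 11.45 ± 0.159). The tropomyosin Tpm2 was 8.13-fold lower, Ssbp4 7.77-fold and the secreted neural factor Tafa1 6.92-fold. Izumo3 was at least 18.3-fold above TO-d in OT-d, and the RNA sensor gene Dhx58 was above background only in TO-d, at least 2.83-fold. In all, 3084 genes were higher and 3401 lower in TO-d, with 263 and 252 over 2-fold, and 3422 were higher and 1712 lower with loess alone. Slides 2 and 3 held samples of either line, and within them the differences correlated at 0.94 and 0.954 with the pooled ones.

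Stress and 1-carbon genes were higher in TO-d than in OT-d. Of 30 integrated stress response genes 24 were higher and 2 lower (median log2 0.84, adjusted p = 2.43e-13; 0.000337 with an estimated correlation). Beside Trib3 these included Nupr1 (log2 1.85), the glutathione-degrading enzyme Chac1 (1.82) and the secreted stress signal Gdf15 (1.71). Of 34 Nrf2 targets 23 were higher and 4 lower (median 0.38, adjusted p = 9.04e-08; 0.00152 with an estimated correlation), with the quinone reductase Nqo1 at log2 2.22 and the heme oxygenase Hmox1 at 1.72. Folate, methionine and serine genes were higher in 19 of 37 and lower in 5 (median 0.27, adjusted p = 0.000452; 0.0414 with an estimated correlation). Aldh1l2, which oxidizes formyl-folate in mitochondria, was at log2 1.93, and Phgdh, the first enzyme of serine synthesis, was 2.83-fold higher (15.12 ± 0.16 against 13.67 ± 0.05). The unfolded protein response was higher in 21 of 38, with Sel1l at log2 1.24 and Hsp90b1 at 0.74 (median 0.33, adjusted p = 5.74e-05; 0.0414 with an estimated correlation). These 4 lists held their call with the estimated correlation. Adjusted over the list alone the higher genes numbered 26, 24, 20 and 24 in that order.

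Antiviral and heat shock genes were also higher in TO-d, and mitotic and catecholamine genes lower. Interferon genes were higher in 23 of 32, 25 adjusted over the list alone, with Rsad2 at log2 2.04 and Ifih1 at 1.90 (median 0.51, adjusted p = 4.39e-10; 0.0808 with an estimated correlation). Heat shock genes were higher in 12 of 24, with Dnajb4 at log2 1.16 (median 0.27, adjusted p = 0.00122; 0.0935 with an estimated correlation). Of 46 mitosis genes 37 were lower and 0 higher, led by the kinesin Kif20a (log2 -1.77), the proliferation marker Mki67 (-1.52) and the cyclin Ccna2 (2.83-fold lower), median -0.86, adjusted p = 1.73e-12 (0.161 with an estimated correlation). Of 25 catecholamine and cholinergic genes 15 were lower, 16 adjusted over the list alone, with the vesicle transporter Slc18a2 at log2 -1.41 and Maoa at -1.24 beside Ddc (median -0.37, adjusted p = 0.00437; 0.057 with an estimated correlation). Slc18a1, the related transporter, was higher at log2 1.55. Matrix genes were higher in 18 of 35, with Fbln2 at log2 1.48 (median 0.28, adjusted p = 0.0325; 0.514 with an estimated correlation). Of 20 cobalamin genes 7 were higher and 0 lower, with the mutase Mmut at log2 0.72 and Mtr at 0.62, and the list did not pass (median 0.12, adjusted p = 0.0514).

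**Figure D2:**
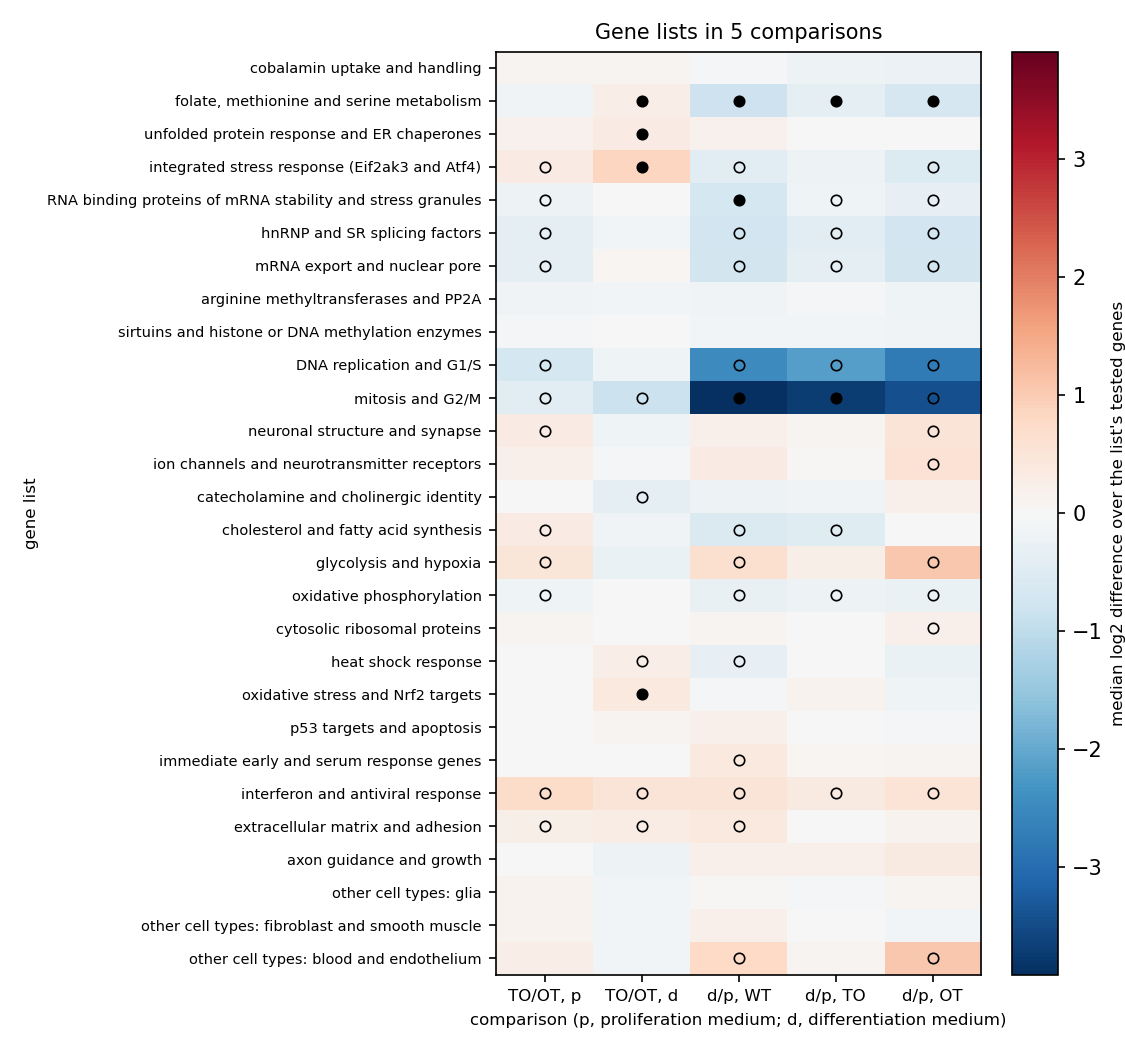
Median log2 difference over the tested genes of each of the 28 gene lists (vertical axis, colour) in 5 comparisons (horizontal axis), with circles where the list's adjusted p was under 0.05 and filled circles where it stayed so with an estimated correlation. The stress response list is at 0.84 in TO-d against OT-d, and mitosis genes are at -3.91, -3.72 and -3.45 in the 3 medium comparisons.

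TO against WT in proliferation medium compares the cobalamin-binding line with the untransfected cells. Dlk1, a membrane ligand that restrains differentiation, was 34.3-fold lower in TO-p (7.10 ± 0.75, SD, n = 4) than in WT-p (12.73 ± 0.241), adjusted p = 1.17e-09. Its level in TO and OT differed with the other sample on the array, at 7.96 to 8.73 in the 6 samples beside a WT sample and 6.19 to 7.01 in the other 10, and without TO-p replicate 1 the fold was 45.1. Wnt2 was 6.22-fold lower, the single-stranded DNA-binding gene Ssbp4 5.78-fold (9.04 ± 0.208 against 11.63 ± 0.131), 5 Magea genes 4.30- to 5.97-fold, Isyna1, which makes inositol, 4.64-fold and Prr9 4.44-fold. Higher genes began with Dpyd at 9.41-fold (11.39 ± 0.37 against 8.14 ± 0.169; adjusted p = 5.39e-16), Slc7a14 at 7.30-fold, Znhit6 at 6.08-fold (14.05 ± 0.145 against 11.40 ± 0.0757) and the mitochondrial ribosome gene Mrps28 at 5.71-fold. Syde2 (5.57-fold), the phosphatase Ptpn18 (5.17-fold), Ddah1 (5.17-fold), which breaks down methylated arginine, the signalling adaptor Bcl10 (5.03-fold), Odf2l (4.27-fold) and the TGF-beta repressor Skil (4.10-fold) came next. Kcnip4 was above background only in WT-p, at least 8.63-fold above TO-p. In all, 3107 genes were higher and 2581 lower in TO-p, with 139 and 102 over 2-fold, and 1998 were higher and 2929 lower with loess alone.

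Among lists, replication genes were lower in TO-p than in WT-p in 32 of 46, with Ung at log2 -0.99 and the repressor E2f8 at -0.80 (median log2 -0.45, adjusted p = 2.65e-10; 0.612 with an estimated correlation), and the median was -0.281 without WT-p replicates 1 and 3. Mitosis genes were lower in 17 of 46 (median -0.26, adjusted p = 0.000262; 0.617 with an estimated correlation), splicing factors in 21 of 52, with Rbm3 at log2 -1.14 against Ptbp2 at 1.54 (adjusted p = 0.00185; 0.612 with an estimated correlation), and export genes in 13 of 62 (adjusted p = 0.0188; 0.617 with an estimated correlation). Neither list was called without WT-p replicates 1 and 3, with medians of -0.0875 (adjusted p = 0.184) and -0.0612 (adjusted p = 0.715). Neuronal genes were higher in 22 of 50, with Nrcam at log2 0.89, Syn2 at 0.69 and Sncg at 0.69 (median 0.22, adjusted p = 0.00351; 0.612 with an estimated correlation), and without these 2 samples the list was not called (median 0.0966, adjusted p = 0.121). Ion channels were higher in 17 of 38, with the potassium channel Kcnc4 at log2 0.59 and the glutamate receptor Gria2 at 0.54 (median 0.19, adjusted p = 0.00185; 0.567 with an estimated correlation). Interferon genes were higher in 15 of 32, with Oas1a 2.84-fold higher (median 0.27, adjusted p = 0.000481; 0.612 with an estimated correlation), and the median was 0.175 without these 2 samples (adjusted p = 0.045). Adjusted over the list alone, 34 replication genes were lower, and 25 neuronal and 17 interferon genes higher. The WT-p samples of replicates 1 and 3, which carry RNA labels 1b and 1, correlated across genes with the OT-p samples at 0.777 and 0.721, about as with their own group (0.744 and 0.739). Without them 3110 genes were called in TO-p against WT-p, and 3165 to 3754 in other alternatives given below. Within slides the differences correlated at 0.797 to 0.898 with the pooled ones.

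TO against WT was also compared in differentiation medium. Dlk1 was 49.5-fold lower in TO-d than in WT-d (7.25 ± 0.981 against 13.25 ± 0.298, SD, n = 4; adjusted p = 4.02e-09). The platelet chemokine gene Pf4 was 10.4-fold lower (6.98 ± 0.116 against 10.41 ± 0.37), Wnt2 9.98-fold, the actin-linked Pdlim4 7.59-fold (7.37 ± 0.0246 against 10.31 ± 0.192), Ssbp4 6.37-fold and the hypoxia gene Ndrg1 5.94-fold (10.92 ± 0.496 against 13.51 ± 0.108). Galnt15, the nucleotidase Entpd2, the corepressor Skor1 and Isyna1 were 5.53- to 5.90-fold lower. Dpyd was 12.6-fold higher (10.93 ± 0.157 against 7.24 ± 0.12), Znhit6 6.44-fold (14.37 ± 0.0472 against 11.70 ± 0.172), Ddah1 5.72-fold and the paraspeckle gene Sfpq 5.00-fold (12.14 ± 0.0914 against 9.81 ± 0.48). Frrs1, the collagen Col24a1, Odf2l, Angpt2, Igsf5 and the atypical kinase C gene Prkci were 4.27- to 4.80-fold higher. Kcnip4 was at least 13.0-fold and the filament-anchoring Lad1 at least 6.85-fold above TO-d in WT-d. In all, 3726 genes were higher and 3841 lower in TO-d, with 213 and 330 over 2-fold. With loess alone 4609 were higher and 1564 lower, and the median of all genes lay at log2 0.10 in place of -0.03.

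Protein folding and stress genes were higher in TO-d than in WT-d. Heat shock genes were higher in 15 of 24, with Hsph1 at log2 1.26, Dnajb1 at 1.23 and Hsp90aa1 at 1.12 (median log2 0.46, adjusted p = 4.41e-05; 0.0764 with an estimated correlation). Stress response genes were higher in 17 of 30, with Atf5 at log2 1.24 and the tRNA synthetase gene Wars at 1.11, while Vegfa was lower at -1.38 (median 0.37, adjusted p = 0.00163; 0.0764 with an estimated correlation). Nrf2 targets were higher in 23 of 34, with Pgd at log2 1.38, while the metallothionein Mt2 was lower at -1.49 (median 0.33, adjusted p = 0.00192; 0.0764 with an estimated correlation). Folate genes were higher in 19 of 37, 20 adjusted over the list alone, with Mthfd1 at log2 1.03 and the purine enzyme Atic at 0.86 (median 0.35, adjusted p = 0.0101; 0.157 with an estimated correlation). Export genes were higher in 27 of 62, with Nup93 at log2 1.00, the importin Kpna2 at 0.98 and the exportin Xpo1 at 0.80 (median 0.21, adjusted p = 0.00192; 0.424 with an estimated correlation). Glycolysis and hypoxia genes were lower in 21 of 39, with Adm at log2 -1.81, Slc2a1 at -1.72 and Pdk1 at -1.68 (median -0.38, adjusted p = 0.00163; 0.54 with an estimated correlation). Immediate early genes were lower in 13 of 27, with Egr2 at log2 -1.51 and Egr1 at -1.14 (median -0.23, adjusted p = 0.0234; 0.424 with an estimated correlation). Markers of fibroblasts and smooth muscle were lower in 7 of 11, with Thy1, which neurons also express, at log2 -1.66 (median -0.33, adjusted p = 0.031; 0.157 with an estimated correlation). Slides 1 and 3 held samples of either line, with correlations of 0.938 and 0.837 with the pooled differences.

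OT against WT compares the line whose fusion has no detectable binding with the untransfected cells. In proliferation medium Dlk1 was 24.6-fold lower in OT-p (7.83 ± 0.979, SD, n = 4) than in WT-p (12.73 ± 0.241), adjusted p = 1.97e-09. The OT-p samples beside a WT sample read 8.04 to 8.73 and OT-p replicate 2, beside OT-d, read 6.44. St3gal1 was 10.7-fold lower (7.32 ± 0.234 against 10.73 ± 0.97), Pcolce 8.71-fold (10.05 ± 0.0535 against 13.16 ± 0.0484; adjusted p = 4.17e-21), Isg15 7.15-fold, Tm7sf2 6.67-fold and Ndrg1 6.24-fold (8.83 ± 0.0545 against 11.52 ± 0.815). WT-p replicates 1 and 3 stood apart in St3gal1 and Ndrg1, with St3gal1 at 9.89 and 9.90 against 11.47 and 11.67 in replicates 2 and 4, and Ndrg1 at 10.84 and 10.80 against 12.18 and 12.28. The selenium-binding genes Selenbp1 and Selenbp2, the aldose reductase relative Akr1b7 and the crystallin Cryba2 were 5.32- to 5.63-fold lower. Gpm6b was 14.9-fold higher (11.14 ± 0.158 against 7.15 ± 0.283; adjusted p = 1.19e-15), the muscle scaffold Pdlim3 5.87-fold, Galnt5 3.77-fold, Bambi 3.64-fold, Arhgap25 3.36-fold, the adhesion gene Flrt3 3.15-fold, Id2, an inhibitor of differentiation factors, 3.08-fold, the sulfotransferase Chst8 2.95-fold and Ddc 2.84-fold. Izumo3 was at least 9.39-fold above WT-p in OT-p, and Kcnip4 at least 8.64-fold above OT-p in WT-p. In all, 3360 genes were higher and 3916 lower in OT-p, with 58 and 295 over 2-fold, and 2050 were higher and 4451 lower with loess alone. Slide by slide the differences correlated at 0.876 to 0.94 with the pooled ones.

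Glycolysis and hypoxia genes were lower in OT-p than in WT-p in 28 of 39, with Bnip3 at log2 -2.28 and Aldoc at -2.29 (median log2 -0.58, adjusted p = 1.4e-05; 0.454 with an estimated correlation), and the median was -0.77 without WT-p replicates 1 and 3. Interferon genes were lower in 20 of 32, including the histocompatibility genes H2-K1 (log2 -2.24) and H2-D1 (-1.41), median -0.30, adjusted p = 0.000395 (0.454 with an estimated correlation). Cholesterol genes were lower in 19 of 36, with Acss2 at log2 -1.15 and Hmgcs1 at -0.82 (median -0.27, adjusted p = 0.0018; 0.454 with an estimated correlation), and stress response genes in 15 of 30, with Trib3 at log2 -1.04 (median -0.24, adjusted p = 0.00193; 0.393 with an estimated correlation). Splicing factors were higher in 28 of 52, with Hnrnpdl at log2 0.62 and Hnrnpu at 0.53 (median 0.24, adjusted p = 0.000149; 0.432 with an estimated correlation). Export genes were higher in 32 of 62, with Ddx39a at log2 0.69 and Nup214 at 0.53 (median 0.21, adjusted p = 0.000144; 0.432 with an estimated correlation), and replication genes in 15 of 46, with Cdc6 and Rpa2 at 0.71 (median 0.19, adjusted p = 0.00183; 0.578 with an estimated correlation). Without WT-p replicates 1 and 3 the medians were -0.399 for cholesterol, -0.408 for stress response and 0.358 for replication genes. Adjusted over the list alone, 29 glycolysis and 21 interferon genes were lower, and 31 splicing and 34 export genes higher.

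OT was compared with WT in differentiation medium too. Tafa1 was 9.74-fold higher in OT-d (10.74 ± 0.171, SD, n = 4) than in WT-d (7.37 ± 0.334), Agtr2 9.29-fold and Ddc 8.75-fold (11.45 ± 0.159 against 8.29 ± 0.154; adjusted p = 6.11e-16). Sfpq was 5.26-fold higher, the neuronal adaptor Nyap2 4.72-fold, the sulfotransferases Chst8 and Chst13 4.56- and 4.31-fold, and Kif26b 6.04-fold, whose other probe went the opposite way. Galnt15 was 9.80-fold lower (7.59 ± 0.258 against 10.95 ± 0.136), Pcolce 7.03-fold, the protease inhibitor relatives Ctla2a and Ctla2b 6.91- and 6.41-fold, the antiviral Rsad2 6.63-fold (7.76 ± 0.0366 against 10.46 ± 0.0284), Tram2 6.08-fold, Osgin1 5.79-fold, Entpd2 5.57-fold, the calcium channel Tmem63a 5.49-fold and the immediate early gene Egr1 5.18-fold. Izumo3 was at least 16.0-fold above WT-d in OT-d, and Kcnip4 at least 11.7-fold above OT-d in WT-d. In all, 4318 genes were higher and 4084 lower in OT-d, with 295 and 393 over 2-fold, and 4384 were higher and 2778 lower with loess alone. Only slide 3 held samples of either line, where the differences correlated at 0.879 with the pooled ones.

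Catecholamine and cholinergic genes were higher in OT-d than in WT-d in 17 of 25, with the lineage factor Gata3 2.84-fold higher, the noradrenaline enzyme Dbh at log2 1.45 and Mycn at 1.04 (median log2 0.44, adjusted p = 5.49e-05; 0.0195 with an estimated correlation). Mitosis genes were higher in 32 of 46, 35 adjusted over the list alone, with Ccna2 at log2 1.72 and Cenpf at 1.60 (median 0.78, adjusted p = 1.36e-08; 0.225 with an estimated correlation). Neuronal genes were higher in 26 of 50, with the neurofilament Nefh at log2 1.62 and Dpysl3 at 1.42 (median 0.32, adjusted p = 0.00126; 0.222 with an estimated correlation). Axon guidance genes were higher in 18 of 32, with Slit2 at log2 1.56 and Plxna4 at 1.54 (median 0.46, adjusted p = 0.00387; 0.101 with an estimated correlation), and cholesterol genes in 19 of 36, with Nsdhl at 1.11 (median 0.39, adjusted p = 0.000566; 0.305 with an estimated correlation). Stress response genes were lower in 16 of 30, with Vegfa at log2 -1.98 and Nupr1 at -1.96 (median -0.30, adjusted p = 0.00079; 0.0837 with an estimated correlation). The p53 targets were lower in 15 of 33, with Gadd45g at log2 -1.31 and the growth inhibitor Cdkn1a at -1.20 (median -0.16, adjusted p = 0.0132; 0.0837 with an estimated correlation). Interferon genes were lower in 20 of 32 (median -0.48, adjusted p = 5.78e-05; 0.225 with an estimated correlation) and matrix genes in 21 of 35, with Fbln2 at log2 -1.96 and Col18a1 at -1.42 (median -0.40, adjusted p = 0.000198; 0.211 with an estimated correlation). Markers of fibroblasts and smooth muscle were lower in 6 of 11, with Col1a1 at log2 -1.31 and Pdgfrb at -1.23, while Acta2 was higher at 0.69 (median -0.38, adjusted p = 0.0289; 0.157 with an estimated correlation).

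Genes in which TO stood apart from the other two lines leave out the differences that TO and OT had in common against WT. In proliferation medium Dpyd was 15.6-fold above OT-p and 9.41-fold above WT-p, and the order went on with Slc7a14, Ddah1, Bcl10, Syde2, Mrps28 and Znhit6, at log2 2.24 to 3.83 above OT-p and 2.33 to 2.87 above WT-p. All of the genes just named have probes on chromosome 3. Lower in TO-p than in both were Wnt2 (log2 -2.82 and -2.64), the Magea genes, Ssbp4 (-2.03 and -2.53), Angptl4 (-2.64 and -2.01) and the neural repressor Prdm8 (-2.13 and -1.62). In all, 2594 genes were higher and 1977 lower in TO-p than in both, with 126 and 52 over 2-fold, and 1766 and 2095 with loess alone. These 4571 genes became 2445 with the pairs of RNA labels averaged, 2862 without the b samples and 2234 without the WT-p samples of RNA label 1. In differentiation medium Dpyd (log2 3.04 and 3.66), Znhit6 (2.35 and 2.69), Bcl10 (2.09 and 2.09), Mrps28 (2.18 and 2.05), Angpt2 (2.03 and 2.11) and the complement protease C1ra (2.20 and 1.93) were higher. Wnt2 (-3.52 and -3.32), Ssbp4 (-2.96 and -2.67), Tpm2 (-3.02 and -2.22), Tmsb4x (-3.55 and -2.11) and Ndrg1 (-2.24 and -2.57) were lower, among 1509 higher and 1526 lower genes, with 65 and 91 over 2-fold, and 1920 and 496 with loess alone.

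The differences of TO from OT and from WT share the TO samples, so they overlap by construction. In proliferation medium the 2594 genes higher and 1977 lower in both compare with 931.7 and 677.9 under independence, and 187 genes were called in opposite directions. The correlation across genes was 0.748 with a covariance of 0.139, against 0.571 and 0.00654 in simulations with no effect, which gave 0 shared genes, and 0.628 to 0.758 and 0.119 to 0.141 when the TO samples were split between the comparisons, which left 2467 to 3737 genes. In differentiation medium the 1509 higher and 1526 lower in both compare with 707.5 and 804.3, and 710 were opposite, with a correlation of 0.428 and covariance of 0.0808 (simulations 0.588 and 0.00869), and 1787 to 2241 genes, 0.353 to 0.441 and 0.0704 to 0.0825 with split samples. Between TO and OT, each against WT, 398 genes were higher and 540 lower in both in proliferation medium, against 642.8 and 622.3 under independence, and 2358 were opposite. The correlation was -0.209 and the covariance -0.0263 (simulations 0.422 and 0.00438), and split WT samples gave 473 to 648 shared genes, -0.475 to 0.0572 and -0.09 to 0.00551. In differentiation medium 2224 were higher and 2174 lower in both, against 990.6 and 965.9, and 559 were opposite, with 0.561 and 0.116 (simulations 0.505 and 0.007), and split samples gave 2671 to 3665 genes, 0.442 to 0.556 and 0.0992 to 0.118.

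**Figure D3:**
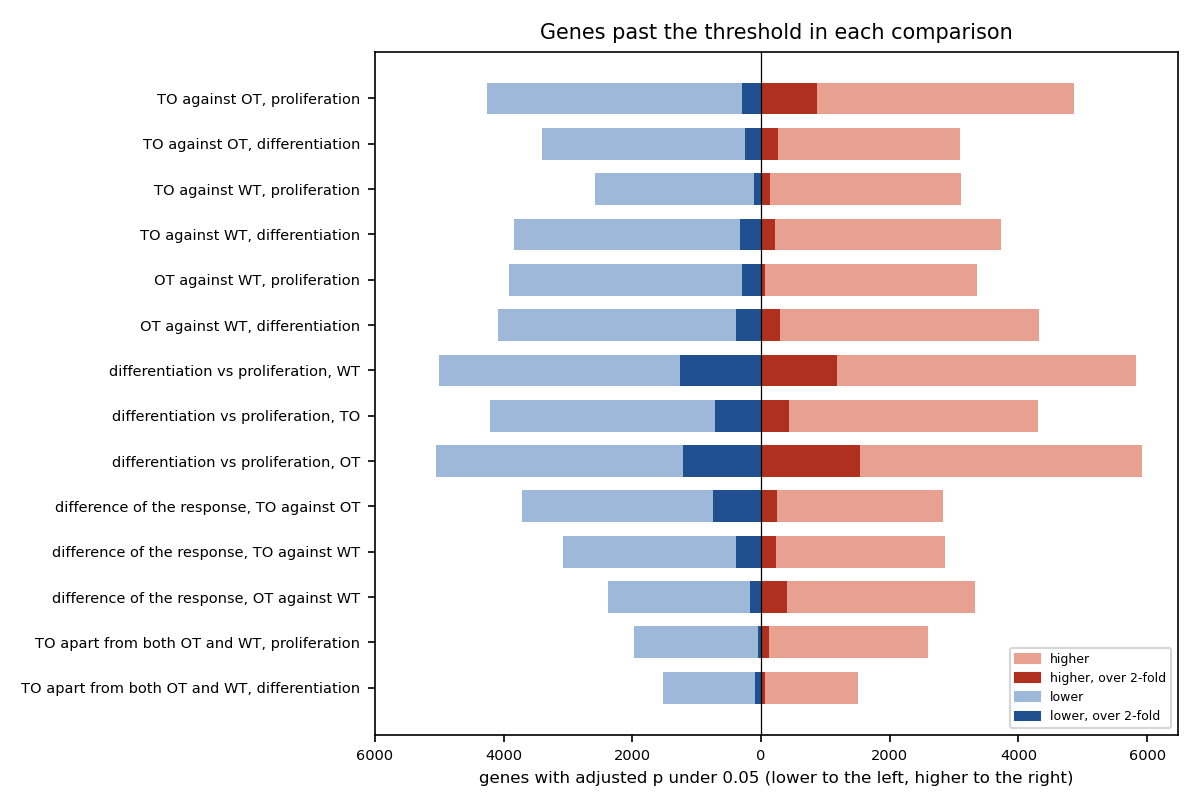
Number of genes with adjusted p under 0.05 (horizontal axis, lower to the left and higher to the right) in each of the 14 comparisons (vertical axis), with darker bars for changes over 2-fold. The medium comparisons in OT and WT call the most genes, 10973 and 10824.

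Differentiation against proliferation medium asks how each line responds to serum reduction with DMSO. In WT the proliferation genes fell furthest, with the exonuclease Exo1 down 56.1-fold (7.38 ± 0.49 in WT-d against 13.19 ± 0.318 in WT-p, SD, n = 4; adjusted p = 2.44e-16), Shcbp1 50.6-fold, Mki67 48.1-fold (7.58 ± 0.411 against 13.28 ± 0.438) and the cyclin Ccnb1 47.2-fold (7.14 ± 0.434 against 12.68 ± 0.262). The cohesin protector Sgo1, the kinase Pbk, Ccna2, the helicase subunit Mcm3, Pclaf and the kinetochore motor Cenpe fell 33.7- to 42.7-fold, and Pclaf fell 54.2-fold without WT-d replicate 4. Tmem130 rose 17.4-fold (11.34 ± 0.175 against 7.08 ± 0.422), the glucose sensor Txnip 14.6-fold (12.45 ± 0.12 against 8.56 ± 0.623), Fn3k, which repairs glycated proteins, 13.5-fold, Tmem140 13.4-fold and the dopamine receptor partner Caly 12.6-fold. The efflux transporter Slc47a1, Galnt15, Elapor1, Osgin1 and Plekhg1 rose 10.2- to 11.9-fold. Ckap2l, Ndc80 and Aspm, all of mitosis, dropped under background by at least 10.1-fold, and Cst12 and Lyz2 rose above it by at least 2.66- and 2.42-fold. In all, 5824 genes rose and 5000 fell, with 1176 and 1252 over 2-fold. With loess alone 3716 rose and 5930 fell, and the median of all genes was log2 -0.07 with loess alone and 0.19 with the processed signals, against 0.06.

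All 46 DNA replication genes fell in WT, with Mcm3 at log2 -5.11 and Mcm5 at -4.47 (median log2 -2.48, adjusted p = 2.49e-25; 0.0837 with an estimated correlation). Without WT-d replicate 4 Mcm5 was at -5.54. Mitosis genes fell in 45 of 46 (median -3.91, adjusted p = 1.93e-30; 0.0331 with an estimated correlation). Folate genes fell in 27 of 37, 28 adjusted over the list alone, with the thymidylate synthase Tyms down 20.5-fold and the serine enzyme Psph at log2 -2.70 (median -0.82, adjusted p = 1.16e-06; 0.0173 with an estimated correlation). Mtr and Mmachc fell too, at log2 -1.28 and -1.26. RNA-binding genes fell in 29 of 43, with the helicase Dhx9 at log2 -1.83, Lin28b at -1.54 and the neuronal Hu gene Elavl4 at -1.31 (median -0.68, adjusted p = 3.77e-05; 0.0331 with an estimated correlation). Splicing factors fell in 44 of 52, with Rbm3 at log2 -3.63 and Srsf1 at -1.99 (median -0.76, adjusted p = 3.48e-09; 0.0837 with an estimated correlation), and export genes in 47 of 62, with Ddx39a at -3.04 and Kpna2 at -2.65 (median -0.72, adjusted p = 5.99e-11; 0.0779 with an estimated correlation). Cholesterol genes fell in 25 of 36 (median -0.56, adjusted p = 1.11e-05; 0.227 with an estimated correlation). Glycolysis and hypoxia genes rose in 26 of 39, with Adm at log2 2.05 (median 0.63, adjusted p = 0.00983; 0.571 with an estimated correlation), but without WT-p replicates 1 and 3 that list was not called (median 0.321, adjusted p = 0.0837). Interferon genes rose in 22 of 32, with Rsad2 at 3.15 and Mx2 at 2.88 (median 0.49, adjusted p = 0.000501; 0.309 with an estimated correlation). All 6 blood and endothelium markers rose, with Vwf at log2 1.24 (median 0.79, or 0.84 with 2 genes at their lower bound, adjusted p = 0.0192; 0.227 with an estimated correlation). Slides 1 and 3 held either medium and correlated at 0.987 and 0.925 with the pooled differences, which include them.

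In TO proliferation genes led the fall, with Mki67 down 47.8-fold (7.62 ± 0.228 in TO-d against 13.13 ± 0.261 in TO-p, SD, n = 4; adjusted p = 1.23e-17), Shcbp1 44.6-fold, Sgo1 41.3-fold, Ccnb1 38.5-fold and the spindle gene Sapcd2 36.4-fold. The survival gene Birc5, Pbk, Cenpe, the condensin Ncapg and the topoisomerase Top2a fell 28.2- to 31.5-fold. Osgin1 rose 15.2-fold (12.20 ± 0.23 against 8.10 ± 0.357; adjusted p = 8.32e-17), Plekhg1 9.93-fold, the recombination gene Rec114 7.63-fold, Tmem140 7.24-fold, the peptidase Ufsp1 5.99-fold, Macrod1 5.91-fold, Mycbpap 5.86-fold, the iron exporter Slc40a1 5.50-fold, Txnip 5.43-fold and the sulfiredoxin Srxn1 5.36-fold. Hmmr fell under background by at least 6.23-fold. In all, 4302 genes rose and 4213 fell, with 438 and 714 over 2-fold, and 4331 rose and 3332 fell with loess alone. All 46 replication genes fell, with Tk1 at log2 -3.87 (median log2 -2.16, adjusted p = 2.03e-28; 0.136 with an estimated correlation), and 45 of 46 mitosis genes (median -3.72, adjusted p = 1.59e-39; 0.0321 with an estimated correlation). Folate genes fell in 24 of 37, with Tyms at log2 -2.59 and Cth at -2.24 (median -0.37, adjusted p = 6.19e-05; 0.0348 with an estimated correlation), splicing factors in 37 of 52 (median -0.42, adjusted p = 1.08e-06; 0.208 with an estimated correlation), export genes in 38 of 62 (median -0.35, adjusted p = 2.35e-07; 0.208 with an estimated correlation) and cholesterol genes in 21 of 36 (median -0.46, adjusted p = 9.9e-05; 0.28 with an estimated correlation). Interferon genes rose in 19 of 32, with Ifit1 at log2 2.37 and Rsad2 at 2.23 (median 0.36, adjusted p = 0.000248; 0.297 with an estimated correlation). On the 3 slides the differences correlated at 0.96 to 0.979 with the pooled ones.

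In OT, Ccdc184 rose 30.2-fold (12.01 ± 0.185 in OT-d against 6.92 ± 0.236 in OT-p, SD, n = 4; adjusted p = 7.04e-17), the ciliary gene Fam183b 24.1-fold, St3gal1 21.6-fold, Ndrg1 20.1-fold (13.10 ± 0.407 against 8.83 ± 0.0545), Txnip 18.9-fold and the acetylcholinesterase Ache 18.3-fold (11.61 ± 0.138 against 7.37 ± 0.381). The cytochrome Cyp2s1, the hypoxia gene Mgarp, the kinesin Kifc2 and Tmem130 rose 15.0- to 16.2-fold. Exo1 fell 30.2-fold, Id2 20.5-fold (9.42 ± 0.156 against 13.83 ± 0.121), the histone H1f5 19.5-fold, and Sgo1, Cenpe, Trip13, Fignl1, Shcbp1 and Ccnb1 18.4- to 19.5-fold. Prr9 fell under background by at least 10.8-fold and E2f8 by at least 6.86-fold. In all, 5923 genes rose and 5050 fell, with 1534 and 1219 over 2-fold, and 5236 rose and 5119 fell with loess alone. Across WT, TO and OT, 2877 genes rose and 2711 fell in every line. For each pair of lines the medium responses correlated at 0.785 to 0.863 across genes, and slides 2 and 3 gave 0.969 and 0.993 with the pooled differences of OT.

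Among the lists in OT, all 46 replication genes fell, with Mcm3 at log2 -4.20 and Rrm2 at -4.08 (median log2 -2.77, adjusted p = 7.85e-25; 0.0848 with an estimated correlation), and 45 of 46 mitosis genes, with Birc5 at -4.01 (median -3.45, adjusted p = 9.6e-26; 0.058 with an estimated correlation). Folate genes fell in 25 of 37, with Tyms at log2 -3.72 and Psat1 at -2.33 (median -0.67, adjusted p = 2.69e-06; 0.0228 with an estimated correlation), splicing factors in 43 of 52 (median -0.74, adjusted p = 1.14e-09; 0.0802 with an estimated correlation) and export genes in 52 of 62, with Rcc1 at -2.20 (median -0.71, adjusted p = 6.91e-12; 0.0598 with an estimated correlation). Neuronal genes rose in 32 of 50, with Eno2 at log2 2.80, Mapt at 2.59 and the granule chaperone Scg5 at 2.32, while Nefh fell at -2.21 (median 0.50, adjusted p = 0.000695; 0.194 with an estimated correlation). Ion channels rose in 22 of 38, with the acetylcholine receptor Chrna5 at log2 1.82 (median 0.56, adjusted p = 0.0148; 0.194 with an estimated correlation), and Th rose at 1.08. Glycolysis and hypoxia genes rose in 29 of 39, with Aldoc at log2 3.81, Bnip3 at 3.44 and Pdk1 at 3.27 (median 1.04, adjusted p = 0.000695; 0.514 with an estimated correlation). Cytosolic ribosomal genes rose in 31 of 59, with Rpl10a at log2 1.10 (median 0.19, adjusted p = 0.0449; 0.531 with an estimated correlation), a call lost in every list alternative but fry, with the opposite sign of the test for the series table and for every spot in the background fit. Interferon genes rose in 17 of 32, with Mx2 at log2 3.06 (median 0.55, adjusted p = 0.0253; 0.514 with an estimated correlation). Blood and endothelium markers rose in 4 of 6, with Lyz2 at log2 2.95, Vwf at 2.13 and the globin Hba-a1 at 1.35 (median 1.05, adjusted p = 0.0272; 0.229 with an estimated correlation).

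The medium response differed between lines in many genes. Between TO and OT 2821 genes were higher and 3719 lower in the response of TO (3102 and 2583 with loess alone), led downwards by Ndrg1, which rose at log2 4.33 in OT against -0.06 in TO (difference -4.39). Nrf2 targets were higher in the response of TO, 21 of 34 genes, with Osgin1 at a difference of log2 2.95, Hmox1 at 1.84 and the glutathione enzyme Gclc at 1.49 (median 0.35, adjusted p = 3.08e-06; 0.00897 with an estimated correlation). Stress response genes were likewise higher in 17 of 30, with Sesn2 at log2 1.11 (median 0.39, adjusted p = 2.72e-05; 0.0295 with an estimated correlation), and folate genes in 17 of 37, with Mthfd1 at 1.77 and Phgdh at 1.53 (median 0.33, adjusted p = 0.000208; 0.0402 with an estimated correlation). Export genes (36 of 62 higher, median 0.42, adjusted p = 1.27e-07; 0.124 with an estimated correlation) and replication genes (24 of 46 higher, median 0.47, adjusted p = 1.92e-07; 0.325 with an estimated correlation) fell less in TO than in OT. Neuronal genes were lower in the response of TO, 27 of 50 genes, with Eno2 at log2 -2.17, Stmn2 at -1.53 and the neuronal tubulin Tubb3 at -1.39 (median -0.51, adjusted p = 5.74e-05; 0.124 with an estimated correlation), as were glycolysis genes, 24 of 39 (median -0.79, adjusted p = 0.000209; 0.409 with an estimated correlation). Adjusted over the list alone, 22 Nrf2, 19 folate, 37 export and 25 replication genes were higher, and 29 neuronal and 26 glycolysis genes lower.

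Against WT, 2855 genes were higher and 3083 lower in the response of TO (4402 and 1079 with loess alone, where the median of all genes was log2 0.13 against -0.04), and 3326 higher and 2373 lower in that of OT (3938 and 994 with loess alone, median 0.10 against 0.00). Without the WT-p samples of RNA label 1, 1866 were higher and 1855 lower in the response of TO. Folate genes fell less in TO than in WT, 21 of 37, with Tyms at a difference of log2 1.77 (median 0.45, adjusted p = 9e-04; 0.0964 with an estimated correlation), export genes likewise in 25 of 62, with Kpna2 at 1.15 (median 0.27, adjusted p = 5.72e-06; 0.184 with an estimated correlation), and replication genes in 21 of 46, with Pola1 at 1.40 (median 0.43, adjusted p = 6.49e-06; 0.423 with an estimated correlation). Without those WT-p samples the medians were 0.291 for folate, 0.15 for export and 0.293 for replication genes. Matrix genes were lower in the response of TO in 18 of 35, with Col18a1 at log2 -1.57 and Col1a1 at -1.56 (median -0.37, adjusted p = 9e-04; 0.265 with an estimated correlation), and blood and endothelium markers in 5 of 6, with Vwf at -1.16 (median -0.39, adjusted p = 0.0185; 0.265 with an estimated correlation). Neuronal genes were higher in the response of OT than in that of WT in 28 of 50, with Syn2 at log2 1.82, Dpysl3 at 1.52 and the growth cone gene Gap43 at 1.31 (median 0.44, adjusted p = 2.29e-07; 0.165 with an estimated correlation). Cholesterol genes were higher in the response of OT in 25 of 36, 28 adjusted over the list alone, with Tm7sf2 at a difference of log2 2.07 and Lss of 2.83-fold (median 0.60, adjusted p = 6e-09; 0.165 with an estimated correlation), and mitosis genes in 23 of 46, with Ccnb2 at 2.12 (median 0.56, adjusted p = 4.93e-05; 0.57 with an estimated correlation). Nrf2 targets were lower in the response of OT in 13 of 34 (median -0.14, adjusted p = 0.0264; 0.174 with an estimated correlation). Of all 147 list calls in the 12 comparisons tested, 14 held with an estimated correlation.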

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

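The number of genes searched for outlying samples was chosen only after the result was seen, and the other tests were planned. The difference between media responses was tested directly, as an interaction in the limma model. Between TO and OT 6540 genes passed, and 1 of 100 splits of the samples gave as many, the real one, with 5864 as the highest other. Between TO and WT 5938 passed, and 2 of 100 splits gave as many, with 6157 as the highest other. Between OT and WT 5699 passed, and 2 of 100 splits gave as many, with 8295 as the highest other. These splits moved samples across lines and media together, so they ask only whether the groups are alike. They cannot show whether the medium responses differ beyond chance, and they took samples that share an RNA label number as separate.

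Genes whose response to differentiation medium differed most between TO and OT are given with the difference in log2, and the adjusted p of each gene in this paragraph was at most 0.000122 by limma. Osgin1 rose at 3.92 in TO against 0.97 in OT (difference 2.953). Angptl4 rose in TO and fell in OT (2.461). The TGF-beta regulators Bambi (2.397) and Fst (2.163) and the phosphatase Dusp2 (2.21) fell further in OT. In the other direction, Ndrg1 rose at 4.33 in OT and not in TO (-4.389), and St3gal1 (-3.548), Aldoc (-3.525), Selenbp1 (-3.489) and Ccdc184 (-3.344) were also lower in the response of TO. Between TO and WT, Sfpq fell at -3.12 in WT against -0.30 in TO (2.823), with its other probe going the opposite way. Pde4dip (2.146), the ribokinase Rbks (2.122), Rapgef5 (2.074) and Ap4s1 (1.91) followed. Galnt15 rose at 3.44 in WT against 0.07 in TO (-3.37), and the protease Prss56 (-2.89), Snhg16 (-2.75), Tram2 (-2.675) and Entpd2 (-2.652) were also lower in the response of TO. Between OT and WT the glycogen phosphorylase Pygl (2.415), the meiotic cohesin Rec8 (2.387), Fam170a (2.364) and Ndrg1 (2.307) were higher in the response of OT. Bambi (-2.673), Galnt15 (-2.632), Osgin1 (-2.402), the adenosine deaminase Ada (-2.29) and Id2 (-2.274) were lower in it.

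Single samples far from the rest of their group were sought with Dixon's ratio of the gap to the range, against its 95% critical value for 4 samples, which chance passes in about 1 of 20 groups. With the share of marked spots, 1 per array, the ratio passed in TO-p replicate 1 (0.845), OT-p replicate 3 (0.84) and WT-d replicate 2 (0.897). Of 212 pairs of a named gene and a group 9 passed, 4.25%, against 5.31% over 96608 such pairs of all genes, and those given here follow. In TO-d replicate 3 Hspa5 was at 15.05 against 15.33 to 15.38 (ratio 0.844), Ndrg1 at 10.18 against 11.12 to 11.24 (0.89) and Rbks at 9.76 against 9.43 to 9.49 (0.831). In WT-d, Osgin1 was at 11.56 in replicate 3 against 11.34 to 11.36 (0.875) and Rbks at 7.65 in replicate 1 against 8.28 to 8.29 (0.987). Plekhg1 was at 7.38 in TO-p replicate 3 against 6.69 to 6.74 (0.921), and Sgo1 at 12.92 in TO-p replicate 4 against 12.57 to 12.62 (0.856). Znhit6 was at 11.52 in WT-p replicate 2 against 11.35 to 11.37 (0.852). Tested were the first 3 genes per direction and ranking and those always read out.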

How the results depend on the processing

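The alternatives with every spot in the background fit and without the WT-p samples of RNA label 1 were chosen only after the result was seen, and the others were planned. The counts of genes past the threshold stayed within 1.5 times the reported value in all 14 comparisons under the processed signals, the series table, quantile normalization, loess alone, no filter, every probe singly, no dye term, slide, no array correlation, trend and robust, and every spot. For TO against WT in proliferation medium the count was 5688, and it was 3165 with the pairs of RNA labels averaged, 3754 without the b samples, 3485 with only the groups compared and 3110 without the WT-p samples of RNA label 1. For TO apart from both lines in proliferation medium it was 4571, against 2445 with pairs averaged, 2862 without the b samples and 2234 without the WT-p samples of RNA label 1. For the medium response of TO against WT it was 5938, against 3721 without those WT-p samples. Averaging the pairs also set the array correlation to 0, and the causes of these drops were not tested.

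With a sample left out, TO against OT gave 8378 to 9028 genes in proliferation and 5286 to 6263 in differentiation medium. TO against WT gave 4059 to 6217 and 6498 to 7599, and OT against WT 5545 to 7586 and 7382 to 8419. The medium response gave 10188 to 10790 genes in WT, 7376 to 8390 in TO and 10073 to 10799 in OT. Its differences gave 5551 to 6735 for TO against OT, 4890 to 6579 for TO against WT and 4827 to 6217 for OT against WT. TO apart from both gave 3242 to 5084 genes in proliferation medium, lowest without WT-p replicate 3, and 2362 to 3058 in differentiation medium. With the replicate number as a block in place of dye, TO against WT in differentiation medium gave 7479 genes against 7567.

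All 687 pairs of a named gene and a comparison that were called kept their direction in every alternative. Without a sample 682 to 687 of them were called, lowest without WT-p replicate 3 or TO-d replicate 4, and the other alternatives ended the call of at most 13, with the b samples left out. Without WT-d replicate 4 the fall of Mcm5 in WT went from log2 -4.47 to -5.54 and that of Pclaf from -5.08 to -5.76. Lost most often were list members near the threshold, such as Hba-a1 in the medium response of TO against WT and Tagln and Ddit4 in TO-d against WT-d. Of 147 list calls, 14 were made with an estimated correlation, and fry, which asks whether a list moves and compares it with no other genes, made 253. Among the 104 lists in the text 19 kept their side of the threshold with an estimated correlation and 85 lost it, and the other alternatives ended at most 5 beside the ribosomal one that follows. Without the WT-p samples of RNA label 1 the splicing, export and neuronal lists in TO against WT in proliferation medium and the glycolysis list in the medium response of WT lost their calls. With every spot the oxidative phosphorylation list in TO against OT in proliferation medium had a median of 0.0212 (adjusted p = 0.287) in place of -0.181. The cytosolic ribosomal list in the medium response of OT had a median of 0.194 (adjusted p = 0.0449), and 0.0134 with the series table (adjusted p = 0.779) and -0.00184 with every spot (adjusted p = 0.613), where its test had the opposite sign. Over the alternatives that list's adjusted p went from 6.87e-05 with fry to 0.779, and the cause was not tested. Signal over background limited what was tested, since 11356 genes were too dim, and a fold against a group under background is a lower bound.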

Other observations

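All the tests of TO-p replicate 4, of the run of neighbouring genes, of copies of chromosome 3 or of a stretch of it, of related genes, of a share of 20%, of carry-over and of the other sample of an array were chosen only after the result was seen, and the tests of whole chromosomes, of the slope and of the splits were planned.

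Genes of chromosome 13 lay higher in TO than in OT, with a median log2 difference of 0.19 over 572 genes in proliferation and 0.25 in differentiation medium, and lower in OT than in WT (-0.17 and -0.17), while TO differed from WT by 0.04 and 0.03. Genes of chromosome 5 lay lower in TO than in OT (-0.14 and -0.14), those of the X chromosome likewise (-0.16 and -0.19), and those of chromosome 8 higher in TO than in WT (0.10 and 0.11). In both media 666 genes were higher in TO than in OT and WT. Chromosome 13 held the most, 77 (13.5% of its tested genes), a top count that 10000 shuffles seldom reached (permutation p = 0.0028). Chromosome 3 held 48 (6.41%), below chromosomes 8 (69) and 11 (72).

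Several of the genes furthest higher in TO were neighbours. On chromosome 3, from 145790574 to 146132463 on mm8, 7 tested genes in a row were above log2 1 in all 4 comparisons of TO with OT and WT. With their mean over these they were Ddah1 (2.32), the putative gene BC060266 (2.44), Bcl10 (2.24), the unnamed transcript 2410004B18Rik (1.98), Syde2 (2.08), and the lysosomal channels Mcoln3 (1.34) and Mcoln2 (1.65). They were named after their values were seen. Just before the run, Znhit6 (2.47) and Col24a1 (2.03) were also higher, with Ccn1 between them and the run at 0.09, and beyond it Ssx2ip was at 0.17. Of the 29 genes above log2 1 in all 4 comparisons 17 lay on chromosome 3, which held 749 of 16101 tested genes with a position, and 9 lay within 1 Mb of the run.

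Chance placement of this run was excluded, since 10000 shuffles of the genes over all positions gave a run of at most 3 (permutation p = 1e-04, the smallest they can give). More copies of all or a long part of chromosome 3 were excluded too, since the longest run of 10 Mb windows with a median over 0.2 in all 4 comparisons was 0. A share of only 0.286 of its genes were alike in name, but probe sequences were not compared, so probes shared between genes stay open. More copies of the short stretch in the TO line may explain the run: the SD over its genes was 0.391, but between the media 6 of the 7 genes differed by under 0.5 and Syde2 by 0.638, so the test did not decide. A biological effect of cobalamin binding on this region was not tested, since the design has 1 TO line.

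TO-p replicate 4 stood apart from the other TO-p samples when every spot entered the background fit, with a mean correlation of -0.169. A failed fit caused by a few spots beside a bright speck is consistent with the value of 0.768 once these were left out. RNA of another sample in its place was excluded, since the processed signals, which do not use that fit, gave 0.74. The design gives no biological explanation, and none was tested.

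The WT-p samples of replicates 1 and 3, whose RNA labels 1b and 1 leave open that they are the same RNA labelled again, correlated with the OT-p samples at 0.777 and 0.721, and replicates 2 and 4 at 0.409 and 0.536. Over 46 genes that differ between OT and WT in differentiation medium, the slope of their difference from replicates 2 and 4 on that of OT-p was 0.141 (SE 0.0396), between the bounds set for RNA of the OT line and for none, which left it undecided. A share of 20% or more was excluded, since Gpm6b was at 6.87 and 7.02 where that share would bring 8.82, and Izumo3 lay under such a level by a difference of -0.916, although Bambi (0.943), Pdlim3 (0.255) and AK027992 (1.14) lay above it and an earlier test, a median of 0.0583 (SD 0.462) over 31 genes higher in OT than in WT in both media, did not decide. Replicate 3 shared its array with TO-p, not OT-p, and correlated with TO-p at 0.463, which cannot exclude a small carry-over from it. Carry-over stays open too for replicate 1, beside an OT-p sample. Replicate 1 lay above replicate 3 by a median of 0.0418 (SD 0.229) over the same 31 genes. A difference in the state of the WT cultures, such as their density, stays open and was not tested.

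In some samples, genes that were dim in their group and abundant in the other sample of the array read higher than in the rest of the group. Dlk1 was at 7.96 to 8.73 in the 6 TO and OT samples on an array with a WT sample and at 6.19 to 7.01 in the other 10. Over genes under log2 8 in the rest of the group and above that by over 3 in the other sample, WT-d replicate 4 lay higher than its group by a median of log2 0.748 over 128 genes, 3.96% of the signal of the OT-p sample beside it. In OT-d replicate 4 this was 2.06% over 62 genes, in TO-p replicate 3 2.82% over 20, in TO-d replicate 4 0.596% over 69 and in TO-d replicate 1 -0.653% over 86.

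The real split of the samples was set against the other splits into groups of the same sizes. For each of the 9 comparisons of 4 samples with 4, 1 of 35 splits gave as many genes, the real one. The real and the highest other count were 9136 and 3932 for TO against OT in proliferation and 6485 and 5 in differentiation medium, 5688 and 4779 and then 7567 and 18 for TO against WT, and 7276 and 3733 and then 8402 and 1821 for OT against WT. For the medium they were 10824 and 4421 in WT, 8515 and 2347 in TO and 10973 and 6586 in OT. Chance was excluded in each at a share under 0.05 with the samples taken as separate, but if the pairs of RNA labels are the same RNA the splits are too few for such a share. For TO apart from both lines, 3 of 100 splits gave as many genes in proliferation medium (4571 real, 4988 the highest other) and 2 of 100 in differentiation medium (3035 and 3712). Those splits mixed all the lines, so they ask whether the lines are alike and cannot decide whether TO stands apart. They too took the pairs of RNA labels as separate.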
